A study of Danio rerio x Danio aesculapii and Danio rerio x Danio albolineatus and Danio rerio x Danio kyathit with 48 samples.

How the data were processed

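RNA from the skin of interspecies Danio hybrids was sequenced, and reads were assigned to the allele of each parent. The mothers were D. rerio (zebrafish), and the fathers were D. aesculapii, D. albolineatus, D. kyathit or D. nigrofasciatus. The hybrids carried membrane-bound fluorescent reporters for a pigment cell type each: pnp4a:mem-mCherry for iridophores, tyrp1b:mem-mCherry for melanophores and aox5:mem-EGFP for xanthophores. Dissociated adult skin was sorted on reporter fluorescence into libraries enriched for 1 cell type, and unenriched whole skin served as the control. The labels give polyA RNA, a SMART-seq2 kit and paired-end Nextera libraries. Each of the 4 hybrids had 4 kinds of library with 3 replicates, numbered 3, 4 and 5, which makes 16 groups and 48 libraries. Each library is called here by its hybrid (named by the father), its kind and its replicate number.

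The deposited values came as a table for the D. rerio allele and a table for the paternal allele, each with 19629 genes given by symbol. In both, the deposited unit is a score: allele read counts that the authors had divided by a size factor per allele column and rounded to whole numbers. Median-ratio size factors recomputed over the 96 allele columns lay between 0.997 and 1.0029, so all columns had been scaled together, and 24 columns showed a visible step between low values. The authors' processing notes name the build GRCz11, featureCounts and DESeq2 1.44.0, without saying what each did. The aligner, the variants used to assign reads to an allele and the filters are not given in the sources used here. Whether the replicates came from separate fish is not given either, so every p-value below measures only the spread between these samples, which may be technical.

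Summed over both alleles, values per library ran from 5173935 to 12500648 (median 6067851), and 12982 to 18665 genes were above 0. Scaled values do not show the original read number, so the depth was estimated from the data. For each library, the spread of the log2 allele ratio around its group's mean, over genes with summed values from 300 to 3000, was set equal to the spread that counting molecules would give. Values divided by the resulting value per molecule are called molecules below. A molecule was worth 7.4 to 493.2, and libraries held 25345 to 1011761 molecules. The median was 157527 in iridophore-enriched, 73345 in melanophore-enriched, 64508 in xanthophore-enriched and 274272 in unenriched libraries. Molecule numbers are estimates that also absorb any real spread between replicates, and PCR copies were not marked. No counting interval or floor per gene is given for that reason.

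A count-based test had been chosen before the data were examined. It was replaced by limma 3.58.1 in R 4.3.3 because the values are not counts. The comparisons, the threshold, the gene lists, the rule for named genes and most alternatives were also chosen before the data were examined. The units, pseudocounts, weights and minimum molecule numbers below were chosen after the files had been seen. An earlier limma version with a fixed pseudocount and a shared spread, and another with weights by level only, were run on the real data first. Tested on simulated data, they gave too many false calls and were replaced. The version used was tuned on simulated data, after real counts under the earlier versions were known.

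For enrichment, the alleles were summed, and log2 of the value plus 20 was fitted with a mean per group over all 48 libraries. The contrast for each pigment cell type was the mean of the 4 within-hybrid differences from unenriched skin, tested for genes whose mean over both kinds was worth 5 or more molecules in the sorted libraries. For the allele tests, the log2 ratio of paternal over D. rerio molecules, each plus 0.5, was centred in each library on its median over genes with 5 or more molecules. Centring removed between -0.068 and 0.798. Because the authors had scaled each allele column, uncentred ratios were in part balanced between the alleles as well. Ratios from fewer than 3 molecules were left out, and mitochondrially encoded genes were not tested. The 12 libraries of a hybrid were fitted together, and a gene was tested in a group if 2 of 3 libraries held 5 or more molecules. Both fits used precision weights from each library's scatter against level (lowess span 0.3) and limma's moderated variances with trend and robust settings. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. F tests asked whether the allele ratio of a gene differed among the 4 kinds of library of a hybrid, or among the 4 hybrids within a pigment cell type. They took genes testable in all 4 groups with 10 or more molecules of each allele and at least 5% from the rarer allele, both summed over the 12 libraries of the test. A gene could thus have a single allele in 1 group. This filter was added after genes with a single allele had been seen among the calls. Genes unequal in all 4 hybrids were those past the threshold in 1 direction in each.

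Total expression was not tested between hybrids, because the number of reads that tell the alleles apart depends on the species pair. Marker values of single unenriched libraries are set against those of other hybrids below as description only. The sum of both alleles counts only such reads.

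Lists were fixed for melanophore, xanthophore and iridophore markers, purine synthesis, pteridine and carotenoid pathways, melanin synthesis and melanosome, pigment pattern genes, keratinocyte, dermal fibroblast and scale-forming, endothelial and mural, leukocyte, erythrocyte, skeletal muscle, glia and neuron, immediate early and heat shock, and mitochondrially encoded genes. Lists with 5 or more tested genes were tested in the enrichment contrasts with limma's camera at the preset correlation and again with an estimated correlation. These were 42 tests at each setting, adjusted within each contrast. Camera compares a list with all other tested genes. Some genes stand on more than 1 list.

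Named genes followed a rule. Reporter genes and chosen pattern genes (kcnj13, igsf11, gja5b, cx39.4, edn3b, csf1a, kitlga, ltk, mitfa, tjp1a) were given wherever tested. Enrichment added the 10 largest rises and the 5 largest falls with 1 sign in all hybrids and a mean log2 CPM of 4 or more, and up to 8 members of the cell type's list. Allele tests added the 3 largest ratios in each direction with 1 sign in 3 of 3 libraries, 10 or more reads of each allele and 100 or more of both, and up to 4 pigment list members. The other tests added the 5 largest or most certain genes and up to 6 or 4 list members. Reads in that rule were taken as molecules. Genes known only by a clone name were passed over. Symbols are those of the tables, and coordinates were not available.

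The method was tested on simulated data with the molecule numbers of the real libraries. False calls made up 0 to 4.9% of calls, and 33.3 to 100% of simulated log2 changes of 2 were recovered. The version used had been tuned on simulated data, and some simulated comparisons held fewer testable genes than the real ones (147 against 680 among kinds in aesculapii). These rates therefore need not hold for the real calls. Of changes of 1, 0 to 80.6% were recovered, with 0% in the test among hybrids in iridophore-enriched libraries, so many changes of that size would be missed. Replicate numbers appear in the labels as a batch. Correlations of residuals between libraries of a hybrid averaged 0.037 for the same number and -0.018 for other numbers in summed values, and 0.009 and -0.004 in allele ratios. Single pairs with the same number reached 0.151 within a hybrid and 0.365 within a cell type in summed values. The main fits had no block, as planned, because no protocol states one, and a block for the number was an alternative. No 2 libraries were identical. For aox6, the ratio in 3 hybrids was also compared among 3 kinds of library by an exact permutation test with Holm's adjustment, which replaced a parametric F test after its values had been seen. The other alternatives were other pseudocounts, filters, centring, scaling, weights, sets of libraries and leaving out each replicate number. The closing section gives their effect. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.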

Results

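The series compared the activity of both parental alleles in pigment cells of hybrid fish whose fathers belonged to species with adult patterns unlike that of zebrafish. There were 36 sorted libraries, 12 for each pigment cell type, and 12 libraries of unenriched skin, with 3 libraries in each of 16 groups. Summed normalised values per library lay between 5173935 and 12500648, and the paternal allele made up 43.94 to 54.86% of them. Each allele column had its own size factor, so a share near equality was set largely by that scaling. The median number of genes above 0 was 16343 in iridophore-enriched, 16455.5 in melanophore-enriched, 15381 in xanthophore-enriched and 17907.5 in unenriched libraries. The summed values of replicate libraries had median Spearman correlations across genes of 0.74, 0.67, 0.64 and 0.80 in that order, where genes are not independent replicates.

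The first question was which genes the sorted cells held above whole skin. In iridophore-enriched libraries, genes of light-reflecting iridophores rose most. The reporter gene pnp4a, a purine nucleoside phosphorylase gene, rose by 5.62 ± 0.36 on the log2 scale (SE), from a normalised value of 825 ± 1181 in unenriched skin to 19310 ± 6073 (SD, n = 12 each, adjusted p = 2.5e-15, above its hybrid's skin mean in 12 of 12 libraries). The lipocalin gene apoda.1 rose by 6.23 ± 0.46, the kinase anchor gene akap12a by 6.21 ± 0.47, the Ly6-family gene lypc by 6.12 ± 0.45 and the defensin gene defbl1 by 5.93 ± 0.48. The LIM-domain genes fhl2a and fhl2b rose by 5.80 ± 0.40 and 5.58 ± 0.44, sytl2b by 5.34 ± 0.37, the melanosomal glycoprotein gene gpnmb by 5.28 ± 0.37 and tmem179b by 5.23 ± 0.32. Of the genes with 1 sign in all hybrids, the largest falls were those of the globin genes hbba1 (-5.01 ± 0.69) and hbaa1 (-4.69 ± 0.68), which have near-identical copies, the protease gene adamts1 (-4.55 ± 0.45), the transcription factor gene irf4b (-4.35) and the retinoic acid hydroxylase gene cyp26b1 (-4.31). Across 5350 genes tested with limma, 1385 rose and 1432 fell, and with recomputed size factors, which moved the median of all genes by 0.086, 1505 rose and 1283 fell.

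Of the 18 iridophore markers tested in these libraries, 17 rose and the connexin gene cx35.4 fell (-1.34 ± 0.29), with a median of 4.67 (18 adjusted over the list alone, adjusted p = 6.63e-14, and 0.0275 with an estimated correlation). Among them were the transcription factor genes tfec (4.89 ± 0.32), alx4a (4.25 ± 0.30) and alx4b (3.37 ± 0.25) and the endothelin receptor gene ednrba (4.05 ± 0.32). Purine synthesis genes, whose products feed the guanine crystals of iridophores, rose in 11 of 16 cases and fell in that of impdh2 (12 adjusted over the list alone, median 1.11, adjusted p = 0.00173, and adjusted p = 0.0813 with an estimated correlation). The largest rises among them were those of atic (2.21 ± 0.26), ppat (1.85 ± 0.25) and paics (1.71 ± 0.23). Of 18 melanin and melanosome genes, 17 rose (18 adjusted over the list alone, median 1.99, adjusted p = 2.12e-09, and 0.016 with an estimated correlation). The largest rises among them were those of rab32a (3.04 ± 0.19), hps3 (2.71 ± 0.23) and hps4 (2.47 ± 0.22), while tyrp1b rose by 1.85 ± 0.64 (adjusted p = 0.0159) and pmela had 1.45 ± 0.69 (adjusted p = 0.0763). Melanophore markers rose in 9 of 13 cases, and slc37a2 fell (10 adjusted over the list alone, median 1.95, adjusted p = 1.79e-05, and adjusted p = 0.0935 with an estimated correlation).

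Xanthophore markers went both ways in the iridophore-enriched libraries: pax7a (3.15 ± 0.32) and slc2a15a (3.02 ± 0.32) were among 5 that rose, and aox5 (-2.03 ± 0.57, adjusted p = 0.00286) and ghrb (-2.83 ± 0.29) among 6 of 14 that fell (11 adjusted over the list alone). Their median was -0.37, whereas the list test pointed upward without passing (adjusted p = 0.817, and 0.914 with an estimated correlation). The pteridine and carotenoid list likewise had 5 that rose and 4 that fell of 15 (9 adjusted over the list alone) and a median of -0.48 against an upward test that did not pass (adjusted p = 0.542, and 0.797 with an estimated correlation). Pattern genes rose in 16 of 22 cases and fell in those of aqp3a and csf1b (18 adjusted over the list alone, median 1.53, adjusted p = 7.77e-06, and adjusted p = 0.0665 with an estimated correlation). Those that rose included the colony-stimulating factor gene csf1a (3.47 ± 0.29), the adhesion gene igsf11 (2.93 ± 0.31), the tight junction gene tjp1a (2.16 ± 0.31), the kit ligand gene kitlga (1.24 ± 0.23), the connexin gene cx39.4 (1.16 ± 0.36) and the receptor kinase gene ltk (0.90 ± 0.27), with adjusted p-values from 2.3e-13 to 0.00641.

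Markers of other skin cells were lower in iridophore-enriched libraries. Of 21 dermal fibroblast and scale genes, 19 fell (19 adjusted over the list alone, median -3.00, adjusted p = 6.63e-14, and 0.016 with an estimated correlation), among them col1a2 (-4.21 ± 0.33) and dcn (-3.59 ± 0.26). Falls reached 22 of 31 keratinocyte genes, with a rise of icn (23 adjusted over the list alone, median -1.23, adjusted p = 7.14e-05, and adjusted p = 0.256 with an estimated correlation), and 19 of 21 leukocyte genes (20 adjusted over the list alone, median -1.74, adjusted p = 3.34e-08, and adjusted p = 0.105 with an estimated correlation). All 6 tested erythrocyte genes fell (6 adjusted over the list alone, median -4.05, adjusted p = 1.7e-05, and adjusted p = 0.0935 with an estimated correlation), as did 5 of 7 endothelial and mural genes (5 adjusted over the list alone, median -1.90, adjusted p = 0.0185, and adjusted p = 0.233 with an estimated correlation). In the muscle list 3 of 5 fell (4 adjusted over the list alone, median -2.22, adjusted p = 0.297, and 0.611 with an estimated correlation). In the glia and neuron list 6 of 8 fell, among them the myelin gene mbpa, and sncga and tubb5 rose (8 adjusted over the list alone, median -1.57, adjusted p = 0.0718, and 0.233 with an estimated correlation). Immediate early and heat shock genes fell in 21 of 31 cases (21 adjusted over the list alone, median -0.83, adjusted p = 7.77e-06, and adjusted p = 0.112 with an estimated correlation), nr4a1 most (-3.83 ± 0.30), and mitochondrially encoded genes in 9 of 13 (11 adjusted over the list alone, median -0.67, adjusted p = 0.00565, and adjusted p = 0.436 with an estimated correlation). The keratin gene krt4 went the other way in kyathit, where the 3 iridophore-enriched libraries held more of it (40652 ± 3290, SD, n = 3) than the 3 unenriched ones (35338, 25389 and 23525).

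In melanophore-enriched libraries the melanin genes rose most. The reporter gene tyrp1b, which acts in melanin synthesis, rose by 6.16 ± 0.59 on the log2 scale (SE), from 1432 ± 2360 to 42717 ± 31264 (SD, n = 12 each, adjusted p = 7.42e-10). The melanosome fibril gene pmela rose by 5.49 ± 0.62, the melanin synthesis genes dct and tyrp1a by 4.66 ± 0.35 and 4.51 ± 0.41 (tyrp1a and tyrp1b are close copies), and mtbl, viml and the chemokine gene cxcl19 by 4.55, 4.14 and 4.03. Further rises were those of tspan10 (3.99), ccdc18 (3.98), grn1 (3.88 ± 0.37), zdhhc2 (3.72), the melanosomal transporter gene slc45a2 (3.11 ± 0.36), syngr1a (2.85) and the melanocortin receptor gene mc1r (2.81 ± 0.35). The largest falls were wisp1b (-3.22 ± 0.46), the myelin gene mbpa (-3.13), hbba1 (-3.05), fgfbp2a (-3.01) and cd248b (-3.00). Across 2740 genes tested, 577 rose and 491 fell, and with recomputed size factors, which moved the median of all genes by 0.113, 694 rose and 373 fell. Without replicate 3 or 4 in every group, 597 and 539 genes passed.

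Of 17 melanophore markers, 16 rose (16 adjusted over the list alone, median 2.78, adjusted p = 3.95e-18, and 0.0146 with an estimated correlation), as did 10 of 11 melanin and melanosome genes (11 adjusted over the list alone, median 2.69, adjusted p = 8.92e-12, and 0.0146 with an estimated correlation). Markers of the other pigment cells were raised as well. Iridophore markers rose in 11 of 12 cases, gpnmb by 2.60 ± 0.38 and pnp4a by 2.28 ± 0.37, and cx35.4 fell (12 adjusted over the list alone, median 2.26, adjusted p = 1.57e-06, and adjusted p = 0.115 with an estimated correlation). Xanthophore markers rose in 9 of 11 cases, slc2a15b by 2.76 ± 0.33, the sodium pump gene atp1a1b fell, and aox5 had 0.86 ± 0.41 with adjusted p = 0.0929 (11 adjusted over the list alone, median 1.15, adjusted p = 0.000401, and adjusted p = 0.157 with an estimated correlation). Pteridine and carotenoid genes rose in 8 of 11 cases (10 adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.14 with an estimated correlation). In the pattern list 10 of 13 rose, csf1a by 1.60 ± 0.32 and kitlga by 1.11 ± 0.24, and cx43 fell (11 adjusted over the list alone, median 1.37, adjusted p = 0.000131, and adjusted p = 0.109 with an estimated correlation). Purine synthesis genes went both ways, 4 up, with the guanine deaminase gene gda at 2.94 ± 0.45, and 2 down of 10 (7 adjusted over the list alone, median 0.09, adjusted p = 0.398, and 0.557 with an estimated correlation).

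Leukocyte genes rose in 10 of 18 cases in the melanophore-enriched libraries and fell in those of ptprc and apoeb (12 adjusted over the list alone, median 0.86, adjusted p = 0.000144, and adjusted p = 0.209 with an estimated correlation). Those that rose most were grn1 and spi1b (2.45 ± 0.24), a transcription factor gene of macrophages, and the antigen presentation gene cd74a, one of a pair of copies, rose by 1.32 ± 0.21 to 33100 ± 8100 (SD, n = 12). Falls came in 20 of 27 keratinocyte genes, against a rise of icn (23 adjusted over the list alone, median -1.52, adjusted p = 1.96e-07, and adjusted p = 0.14 with an estimated correlation), and in 13 of 17 dermal fibroblast and scale genes, against a rise of fn1b (14 adjusted over the list alone, median -1.07, adjusted p = 5.33e-06, and adjusted p = 0.115 with an estimated correlation). In the glia and neuron list 4 of 6 fell and sncga rose (5 adjusted over the list alone, median -1.13, adjusted p = 0.0758, and 0.209 with an estimated correlation). Immediate early and heat shock genes fell in 18 of 31 cases, and hspb1 rose (23 adjusted over the list alone, median -0.62, adjusted p = 2.18e-06, and adjusted p = 0.115 with an estimated correlation). Of 10 mitochondrially encoded genes, mt-co1 fell (1 adjusted over the list alone, median -0.13, adjusted p = 0.302, and 0.702 with an estimated correlation).

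In xanthophore-enriched libraries, genes of pteridine and carotenoid pigments were among the largest rises. The reporter gene aox5, an aldehyde oxidase gene, rose by 2.31 ± 0.43 on the log2 scale (SE), from 590 ± 363 to 2800 ± 2000 (SD, n = 12 each, adjusted p = 0.000225). Larger rises were those of the seipin-like gene bscl2l (2.98 ± 0.44), the sepiapterin reductase gene sprb (2.95 ± 0.50), the carotenoid oxygenase gene bco1 (2.91 ± 0.40), the urate pathway gene uraha (2.89 ± 0.33), akr1b1 (2.87), the pteridine synthesis gene gch2 (2.85 ± 0.49), the lipid droplet gene plin6 (2.85 ± 0.34) and rasd1 (2.76). The aldehyde oxidase gene aox6, a close copy of aox5, rose by 2.75 ± 0.33, the xanthophore transcription factor gene pax7b by 2.61 ± 0.37 and slc22a7a by 2.42. The largest falls were hbba1 (-3.43 ± 0.67), hbaa1 (-2.84), sla2 (-2.60), adgrg1 (-2.46) and the keratin gene krt1-19d (-2.43, adjusted p = 0.0316). Across 2367 genes tested, 271 rose and 161 fell, and with recomputed size factors, which moved the median of all genes by 0.145, 407 rose and 109 fell. Without replicate 3, 4 or 5 in every group, 132, 50 and 277 genes passed.

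All 10 tested pteridine and carotenoid genes rose (10 adjusted over the list alone, median 2.58, adjusted p = 1.68e-15, and 0.00802 with an estimated correlation), as did 9 of 10 xanthophore markers (9 adjusted over the list alone, median 2.73, adjusted p = 6.18e-12, and 0.0247 with an estimated correlation). The reporter genes of the other cell types did not pass, tyrp1b at 0.59 ± 0.84 (adjusted p = 0.649) and pnp4a at 1.11 ± 0.47 (adjusted p = 0.0932, 0.0397 with a block for the replicate number and 0.00688 to 0.415 over the alternatives). Melanophore markers rose in 6 of 9 cases, mlpha by 2.04 ± 0.39 (6 adjusted over the list alone, median 0.98, adjusted p = 0.000122, and adjusted p = 0.112 with an estimated correlation), melanin and melanosome genes in 3 of 6 (3 adjusted over the list alone, median 0.78, adjusted p = 0.00598, and adjusted p = 0.149 with an estimated correlation) and pattern genes in 5 of 8 (5 adjusted over the list alone, median 1.02, adjusted p = 0.000364, and adjusted p = 0.07 with an estimated correlation). Iridophore markers rose in 3 of 12 cases (3 adjusted over the list alone, median 0.30, adjusted p = 0.074, and 0.524 with an estimated correlation) and purine synthesis genes in those of paics and shmt1 of 9 (5 adjusted over the list alone, median 0.37, adjusted p = 0.103, and 0.326 with an estimated correlation). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone, median 1.19, adjusted p = 1.28e-12, and adjusted p = 0.0708 with an estimated correlation), and they took 5.99 ± 2.55% of the summed value, against 3.01 ± 1.53% in unenriched skin (SD, n = 12 each).

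Among the markers of other skin cells, 9 of 16 dermal fibroblast and scale genes fell in xanthophore-enriched libraries (11 adjusted over the list alone, median -0.88, adjusted p = 1.63e-06, and adjusted p = 0.103 with an estimated correlation). Keratinocyte genes rose in 3 and fell in 2 of 29 cases (5 adjusted over the list alone, median -0.40, adjusted p = 0.0567, and 0.555 with an estimated correlation). Of 18 leukocyte genes, marco, spi1b and spi1a rose and ptprc fell (4 adjusted over the list alone, median 0.31, adjusted p = 0.17, and 0.631 with an estimated correlation). The myelin gene mbpa fell among 5 glia and neuron genes (3 adjusted over the list alone, median -0.72, adjusted p = 0.0339, and adjusted p = 0.13 with an estimated correlation). Immediate early and heat shock genes fell in 8 of 31 cases (9 adjusted over the list alone, median -0.31, adjusted p = 1.75e-05, and adjusted p = 0.13 with an estimated correlation). In the melanophore and xanthophore contrasts, too few endothelial, erythrocyte and muscle genes could be tested for a list test. Pigment cell markers were uneven among unenriched libraries. In kyathit 5 and nigrofasciatus 3, pnp4a stood at 3694 and 2808 against a median of 245.5 in the other 10, and tyrp1b at 7217 and 5218 against 220. Without these 2 libraries, 2827, 1070 and 445 genes passed in the iridophore, melanophore and xanthophore contrasts.

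**Figure D1:**
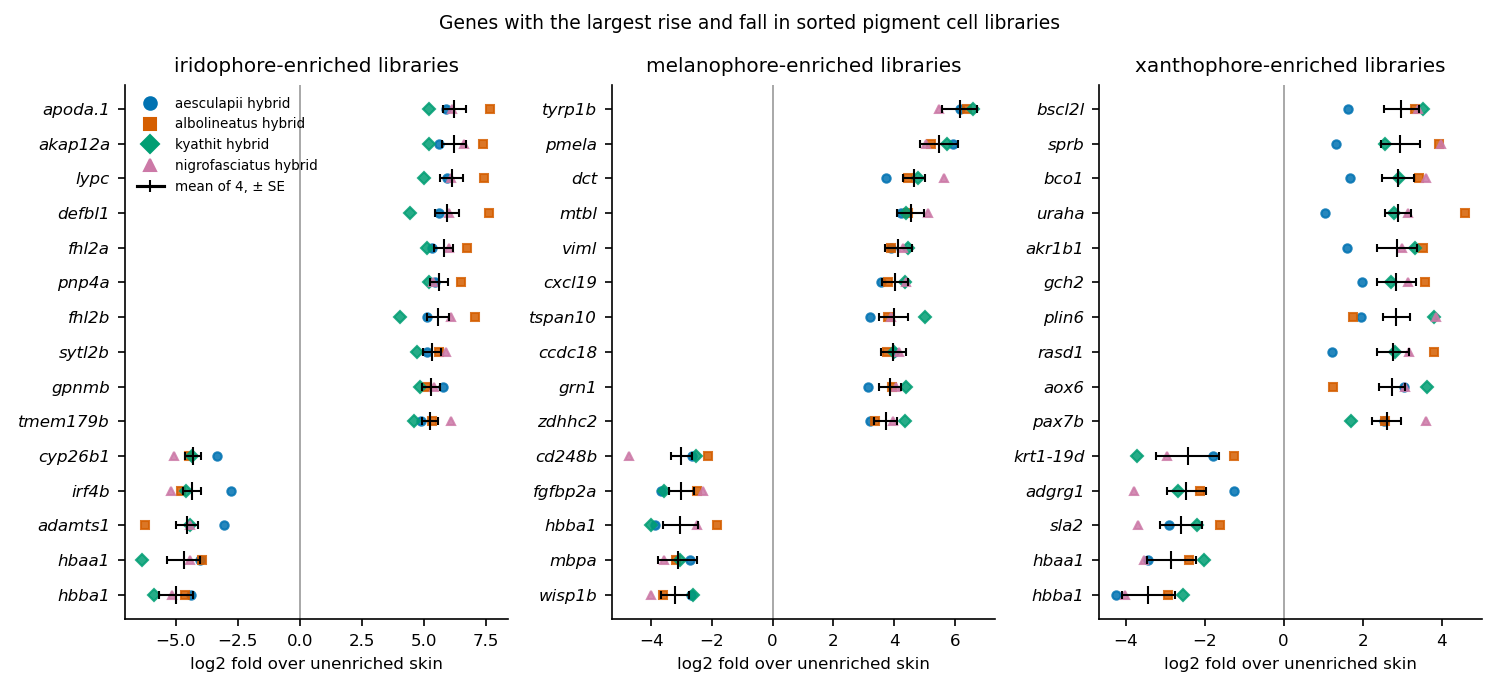
Log2 fold over unenriched skin (horizontal axis) of the 10 genes with the largest rises and the 5 with the largest falls in iridophore-, melanophore- and xanthophore-enriched libraries; coloured points are the 4 hybrids, and the black mark with its bar is their mean ± SE. The largest mean rises are apoda.1 (6.23), tyrp1b (6.16) and bscl2l (2.98), and hbba1 falls in all 3 panels.

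The next question was which genes the hybrids expressed unequally from their D. rerio and paternal alleles, which share every cell and library. In iridophore-enriched libraries some iridophore genes were unequal, in both directions. In the aesculapii hybrid, the endothelin receptor gene ednrba was higher from the paternal allele by 2.24 ± 0.32 on the log2 scale (SE, n = 3, adjusted p = 0.000123, 3 of 3 libraries), and the reporter gene pnp4a from the D. rerio allele (-0.63 ± 0.13, adjusted p = 0.00262, 3 of 3). In the albolineatus hybrid, lypc was lower from the paternal allele by 2.93 ± 0.08 (-2.93, 14372 ± 2597 against 113631 ± 7265, SD, adjusted p = 1.27e-14), and pnp4a also favoured D. rerio (-0.85 ± 0.14). In the kyathit and nigrofasciatus hybrids pnp4a instead favoured the paternal allele (0.79 ± 0.12 and 0.61 ± 0.11). Counts of genes past the threshold, all tested with limma, were 198 paternal and 227 D. rerio of 2259 in the aesculapii hybrid, 449 and 570 of 4424 in albolineatus, 1023 and 1088 of 8129 in kyathit, and 532 and 674 of 4300 in nigrofasciatus. Without centring the nigrofasciatus counts were 647 and 592, so the direction of the surplus there rested on centring. Genes were tested only with enough molecules, so these counts do not rank the species.

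Ratios were ranked only among genes with 10 or more molecules of each allele and 100 or more of both. Among the largest paternal ratios so ranked in iridophore-enriched libraries were the kinase regulator gene pik3r3b in aesculapii (2.80 ± 0.32), esyt1b in albolineatus (3.64 ± 0.26), the steroid dehydrogenase gene hsd17b7 in kyathit (5.72 ± 0.92) and the adenosine deaminase gene ada in nigrofasciatus (3.58 ± 0.36). The D. rerio value of hsd17b7 was 297 ± 475 (SD, n = 3), so it came mostly from a single library and that ratio is uncertain. The largest D. rerio ratios so ranked included thy1, a membrane glycoprotein gene, in aesculapii (-3.39 ± 0.24), jdp2b in albolineatus (-4.43 ± 0.16), the keratin gene krt18a.1, one of several close copies, in kyathit (-3.86 ± 0.20) and the thymosin gene tmsb1, also with close copies, in nigrofasciatus (-4.91 ± 0.21). Pigment genes of other lists were unequal in these libraries too. The libraries were enriched rather than pure, so which cells gave these reads is not known. The melanosomal transporter gene slc45a2 (2.75 ± 0.33) and the guanine deaminase gene gda (2.67 ± 0.51) favoured the albolineatus allele. The melanosome gene bloc1s6 stood at 947 ± 392 from D. rerio and 1.67 ± 1.15 from nigrofasciatus (SD, n = 3), and the thyroid hormone receptor gene thrab stood at 568 ± 354 from D. rerio and was listed at 0 for the kyathit allele in all 3 libraries. An alignment preference for the D. rerio sequence could also give paternal values this low, which was not tested. Of the iridophore markers, 3 paternal and 6 D. rerio of 16 passed in aesculapii (11 adjusted over the list alone), 5 and 4 of 19 in albolineatus (10 adjusted over the list alone), 6 and 7 of 20 in kyathit (14 adjusted over the list alone) and 5 and 3 of 19 in nigrofasciatus (10 adjusted over the list alone). Leaving out each replicate number in turn gave 192 to 421 genes in aesculapii, 547 to 891 in albolineatus, 1197 to 1362 in kyathit and 431 to 1067 in nigrofasciatus.

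Genes of the adult stripe pattern were among those with unequal alleles. The adhesion gene igsf11 favoured D. rerio in iridophore-enriched libraries of the albolineatus (-2.41 ± 0.51, adjusted p = 0.00393) and nigrofasciatus hybrids (-2.74 ± 0.43, adjusted p = 0.00174) and stood at -0.34 ± 0.30 in kyathit (adjusted p = 0.445). The albolineatus and nigrofasciatus alleles of igsf11 held 3.4 and 2.9 molecules over 3 libraries, so the size of these ratios depends in part on the pseudocount. The colony-stimulating factor gene csf1a favoured the paternal allele in iridophore-enriched libraries of aesculapii (0.93 ± 0.26, adjusted p = 0.0218) and albolineatus (0.94 ± 0.29, adjusted p = 0.026) and in melanophore-enriched libraries of nigrofasciatus (2.49 ± 0.27, adjusted p = 3.62e-05). The kit ligand gene kitlga favoured the paternal allele in albolineatus (1.59 ± 0.26, adjusted p = 0.000301) and kyathit iridophore-enriched libraries (0.69 ± 0.18, adjusted p = 0.0104, but 0.0544 with a block for the replicate number and 0.00924 to 0.166 over the alternatives). In the kyathit libraries the connexin gene cx39.4 (1.26 ± 0.41, adjusted p = 0.0367) and the receptor kinase gene ltk (1.20 ± 0.31, adjusted p = 0.014, but 0.0542 with the block and 0.00912 to 0.14 over the alternatives) also favoured the paternal allele. The tight junction gene tjp1a passed in 0 of the 5 groups where limma tested it (largest distance from 0, -0.67 ± 0.34), and kcnj13, gja5b, edn3b and mitfa had too few molecules in every group. Over all groups, unenriched skin included, csf1a passed for the paternal allele in 3 of 14, kitlga in 2 of 13, ltk in 2 of 6 and cx39.4 in 1 of 9, and igsf11 for D. rerio in 2 of 3. The reporter genes passed in 8 of 15 groups for pnp4a (5 paternal; in unenriched albolineatus skin adjusted p = 0.0477, but 0.0847 with the block and 0.044 to 0.375 over the alternatives), 3 of 14 for tyrp1b (0 paternal) and 1 of 13 for aox5 (paternal, in unenriched albolineatus skin, adjusted p = 0.0259, but 0.057 with the block and 0.000539 to 0.184 over the alternatives).

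In melanophore-enriched libraries, some melanin genes were unequal in some hybrids. In the albolineatus hybrid dct favoured D. rerio (-2.25 ± 0.54, n = 3, adjusted p = 0.0123) and slc45a2 the paternal allele (2.30 ± 0.49, adjusted p = 0.0041). In kyathit the melanosome transport gene mlpha (-3.04 ± 0.44) and tspan10 (-2.11 ± 0.49) favoured D. rerio, and in nigrofasciatus the protease gene bace2 did (-2.55 ± 0.35). The rarer alleles of dct, slc45a2 and mlpha held 3.3, 3.4 and 3 molecules, so the size of these ratios depends in part on the pseudocount. The reporter gene tyrp1b lay close to equality, at -0.01 ± 0.14, -0.18 ± 0.18, 0.31 ± 0.13 and -0.28 ± 0.08 in aesculapii, albolineatus, kyathit and nigrofasciatus, and passed in the last (adjusted p = 0.031, but 0.0607 with a block for the replicate number). Uncentred ratios also ended that call (adjusted p = 0.243), and the adjusted p ran from 0.00178 to 0.481 over the alternatives. Counts past the threshold were 91 paternal and 136 D. rerio of 1959 in aesculapii, 132 and 202 of 2335 in albolineatus, 255 and 282 of 2763 in kyathit, and 202 and 348 of 2911 in nigrofasciatus. Of the melanophore markers, 0 of 13 passed in aesculapii with limma (2 at an unadjusted p under 0.05), 1 paternal and 2 D. rerio of 15 in albolineatus (3 adjusted over the list alone), 1 and 4 of 16 in kyathit (6 adjusted over the list alone) and 2 and 4 of 17 in nigrofasciatus (7 adjusted over the list alone).

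Among genes with 10 or more molecules of each allele and 100 or more of both, the largest paternal ratios in melanophore-enriched libraries were the reductase gene ptgr1 in aesculapii (2.36 ± 0.26), the ferritin gene fthl28 in albolineatus (3.49 ± 0.28, with close copies), epdl1 in kyathit (3.67 ± 0.28) and the translation factor gene eif4a1a in nigrofasciatus (3.01 ± 0.39). The largest D. rerio ratios among these were the matrix gene postnb in aesculapii (-3.23 ± 0.28), serpinf1 in albolineatus (-3.67 ± 0.43), the chemokine gene cxcl19 in kyathit (-3.62 ± 0.21) and grn1 in nigrofasciatus (-5.46 ± 0.36). Actin gene actb2, which has close copies, favoured D. rerio in nigrofasciatus (-2.72 ± 0.07). Without centring, the nigrofasciatus counts were 274 paternal and 283 D. rerio and the albolineatus counts 179 and 167, so the direction of the surplus there rested on centring in albolineatus and its size in nigrofasciatus. Leaving out each replicate number in turn gave 103 to 196 genes in aesculapii, 182 to 313 in albolineatus, 193 to 366 in kyathit and 176 to 437 in nigrofasciatus.

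In xanthophore-enriched libraries, some genes of the pteridine pathway were unequal. The aldehyde oxidase gene aox6 favoured D. rerio in all 4 hybrids, by -4.74 ± 0.50, -2.87 ± 0.63, -2.51 ± 0.26 and -4.14 ± 0.26 in aesculapii, albolineatus, kyathit and nigrofasciatus (n = 3 each, adjusted p from 5.3e-07 to 0.0079). The first of these came from under 1 paternal molecule, so its size was set largely by the pseudocount. Those of albolineatus and nigrofasciatus rested on 3.4 and 4.8 paternal molecules, so their size depends on it in part. The purine synthesis gene paics favoured the paternal allele in all 4 (1.75 ± 0.52, 1.25 ± 0.26, 1.79 ± 0.34 and 1.52 ± 0.28, largest adjusted p = 0.0423). The sepiapterin reductase gene sprb favoured D. rerio in albolineatus (-3.07 ± 0.39, adjusted p = 8.11e-05, from 3.1 paternal molecules), and pax7b the paternal allele in nigrofasciatus (2.23 ± 0.36, adjusted p = 0.000916). The reporter gene aox5 did not pass in any hybrid (-0.69 ± 0.45, 0.01 ± 0.51, -0.85 ± 0.30 and -0.47 ± 0.27, adjusted p from 0.0653 to 0.995). Other large ratios were those of mvp in aesculapii (-3.21 ± 0.36), the keratin gene krt5 in albolineatus (2.80 ± 0.54) and kyathit (3.18 ± 0.75), foxd3, a neural crest transcription factor gene, in kyathit (-2.51 ± 0.53) and the chaperone gene clu in nigrofasciatus (-3.47 ± 0.29).

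Counts past the threshold in xanthophore-enriched libraries were 30 paternal and 51 D. rerio of 922 in aesculapii, 94 and 183 of 2178 in albolineatus, 210 and 262 of 3152 in kyathit, and 158 and 271 of 1834 in nigrofasciatus, where uncentred ratios gave 225 and 224. In the other hybrids they gave 31 and 41 in aesculapii, 104 and 136 in albolineatus and 222 and 261 in kyathit. Part of the albolineatus surplus thus rested on centring too. Of the pteridine and carotenoid genes, 1 paternal and 1 D. rerio of 8 passed in aesculapii (2 adjusted over the list alone), 1 and 2 of 10 in albolineatus (5 adjusted over the list alone), 3 and 2 of 11 in kyathit (6 adjusted over the list alone) and 1 and 4 of 10 in nigrofasciatus (5 adjusted over the list alone). Of the xanthophore markers, limma called 0 of 7 in aesculapii and 0 of 10 in albolineatus (0 and 1 at an unadjusted p under 0.05), 2 paternal of 12 in kyathit (3 adjusted over the list alone), and 3 paternal and 2 D. rerio of 13 in nigrofasciatus (5 adjusted over the list alone). Leaving out each replicate number in turn gave 29 to 83, 137 to 167, 140 to 304 and 157 to 317 genes in that order of hybrids.

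**Figure D2:**
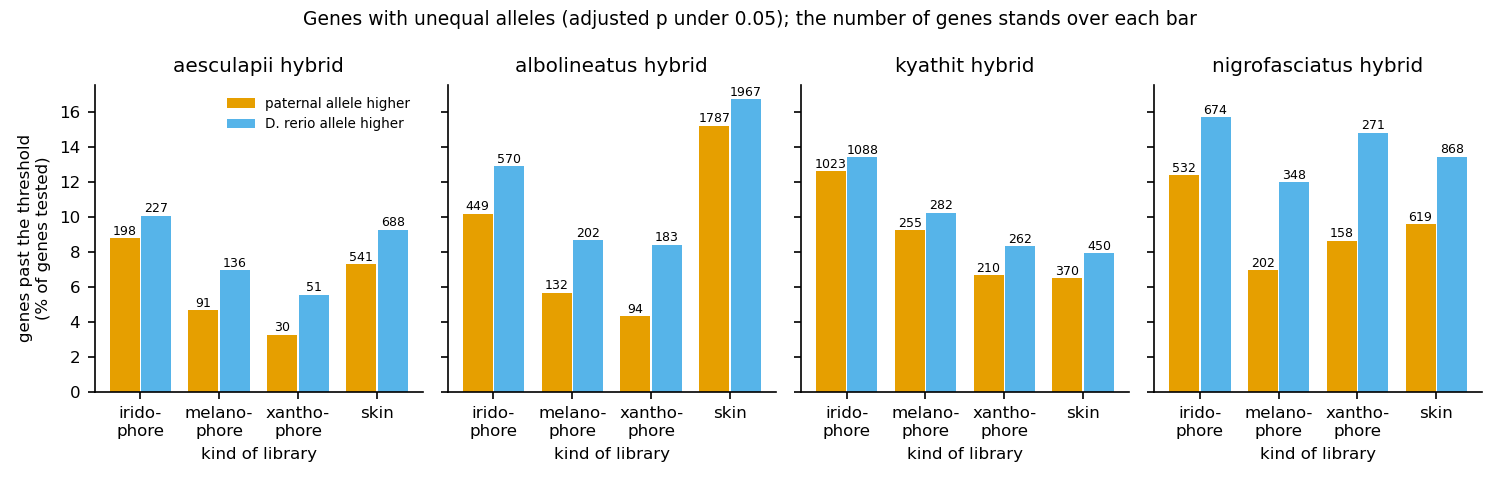
Percent of tested genes (vertical axis) with unequal alleles at an adjusted p under 0.05, by hybrid and kind of library; bars show genes higher from the paternal and from the D. rerio allele, and the numbers over them are gene counts. Shares of all tested genes ran from 8.8 to 31.9%, and the largest count is that of unenriched albolineatus skin, with 1787 paternal and 1967 D. rerio.

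The D. rerio allele was also compared with the paternal alleles of all 4 species at once, which asked for genes unequal in 1 direction in every hybrid. In iridophore-enriched libraries 21 genes favoured the paternal and 45 the D. rerio allele in all 4 hybrids, of 2049 tested in all 4, where independent calls would give 1.97. That number gives every gene the same probability of a call, although molecule numbers differ between genes. All 4 ratios also share the D. rerio allele, so it is not a chance level. The growth factor gene mdkb favoured the paternal allele by 2.76 ± 0.49, 4.91 ± 0.25, 4.40 ± 0.22 and 7.04 ± 0.21 (aesculapii, albolineatus, kyathit, nigrofasciatus; SE, n = 3 each), and the chloride channel gene cftr, the profilin gene pfn2, snap23.1 and mapre2 did so by at least 1.52. The largest mean D. rerio ratios were those of kctd12.1 (-4.15 ± 0.40, -4.93 ± 0.50, -4.82 ± 0.59 and -3.75 ± 0.45, the second from under 1 paternal molecule and so set largely by the pseudocount), ube3d, the thioredoxin gene txn, thy1 and myg1, whose aesculapii allele was listed at 0. Of the pigment genes, lypc (-0.91 ± 0.06, -2.93 ± 0.08, -0.91 ± 0.07 and -2.25 ± 0.06) and gpnmb (-0.36 ± 0.12, -1.58 ± 0.18, -1.64 ± 0.09 and -1.34 ± 0.23) favoured D. rerio, and akap12a the paternal allele by small amounts (0.26 ± 0.08, 0.34 ± 0.10, 0.33 ± 0.08 and 0.57 ± 0.05). With a block for the replicate number, the aesculapii calls of gpnmb (adjusted p = 0.0388) and akap12a (0.03) and the kyathit call of atp1a1b (0.0186) ended, at 0.179, 0.104 and 0.107. Over the alternatives these ran from 0.0103 to 0.568, 0.00316 to 0.517 and 0.0159 to 0.392.

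In melanophore-enriched libraries 6 paternal and 17 D. rerio genes passed in all 4 hybrids, of 1491 (0.3 from independent calls). The limit of such numbers given above holds here and for xanthophore-enriched libraries. The growth arrest gene btg2 favoured the paternal allele (1.66 ± 0.20, 1.71 ± 0.20, 0.85 ± 0.16 and 1.51 ± 0.15), as did fthl28, midn, ywhaz and zfp36l1a. The chemokine gene cxcl19 favoured D. rerio (-2.60 ± 0.42, -3.87 ± 0.43, -3.62 ± 0.21 and -4.42 ± 0.47), with emilin2a, the class I antigen gene mhc1zba, the heat shock gene hsp70.3 (both with close copies), lypc and acp5a, whose kyathit allele was listed at 0. In xanthophore-enriched libraries 7 paternal and 11 D. rerio genes passed, of 792 (0.16 from independent calls), among them aox6, cyp8b3, hsp70.2, hsp70.3 and hsp70l for D. rerio and paics, krt5, eif4a1a, midn and mhc1uka for the paternal allele. Without replicate 3, 4 or 5, 5, 3 and 7 genes passed there, 15, 13 and 12 in melanophore-enriched and 46, 26 and 28 in iridophore-enriched libraries, where fewer libraries also meant fewer genes tested. Hybrids correlated across genes in their ratios with r from 0.30 to 0.42, and kinds of library within a hybrid with r from 0.61 to 0.83, where genes are not independent replicates. A gene whose reads align better to the only build named, that of D. rerio, would also be called for D. rerio in all 4. Because D. rerio was the mother of every hybrid, the species of an allele and its parent of origin cannot be told apart in either direction.

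**Figure D3:**
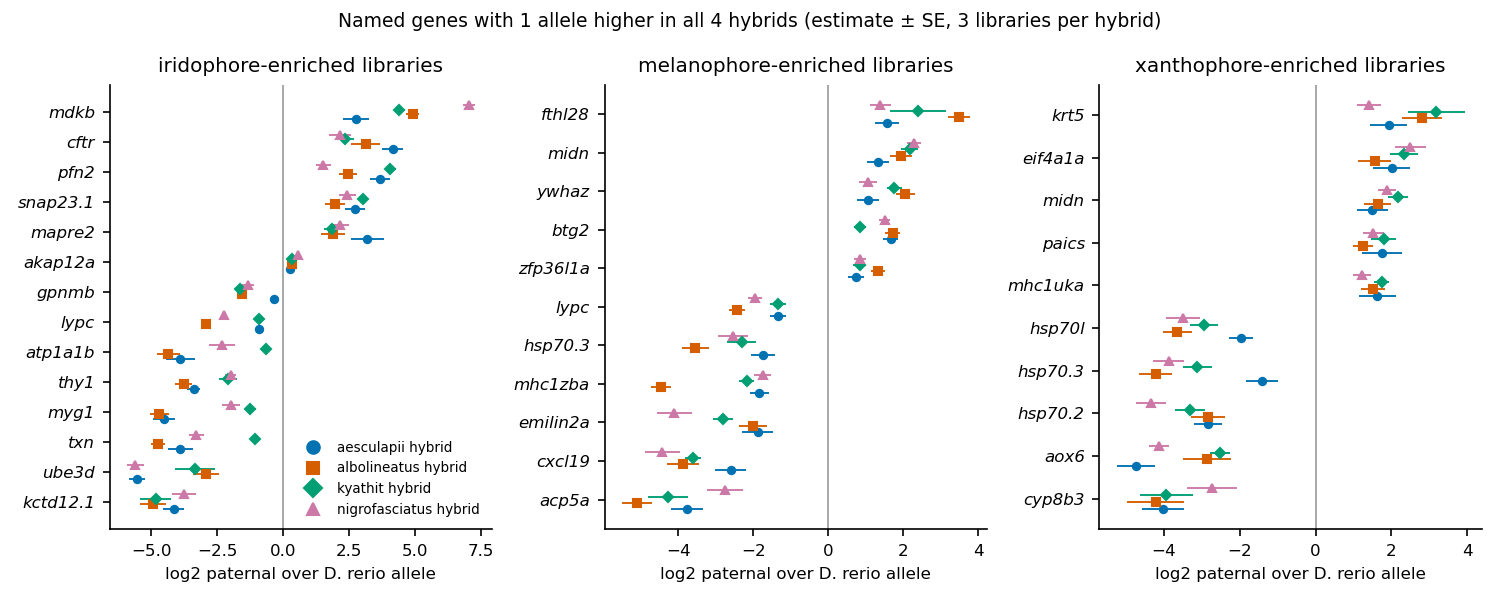
Log2 ratio of paternal over D. rerio allele (horizontal axis) ± SE of the named genes unequal in 1 direction in all 4 hybrids, by kind of sorted library; coloured points are the hybrids. The ratios of mdkb reach 7.04, and those of kctd12.1 lie below 0 in all 4 hybrids.

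A further question was whether the assigned allele ratio of a gene differed among the kinds of library within a hybrid. The glutamine synthetase gene glula, one of 3 close copies, did so in all 4: its paternal allele had its lowest ratios in iridophore-enriched libraries (-1.48, -2.40, -0.81 and -2.54 in aesculapii, albolineatus, kyathit and nigrofasciatus), against those in melanophore-enriched (0.77, 1.45, 1.32 and 0.35), xanthophore-enriched (1.17, 1.35, 1.55 and 0.67) and unenriched libraries (0.68, 1.16, 0.97 and -0.35), with 3 libraries per group and adjusted p = 0.000369, 3.94e-06, 0.00669 and 0.0171. In the nigrofasciatus melanophore-enriched libraries, glula was above 0 in 1 of 3 (1.97, -0.63 and -0.41). In kyathit the order held for group means but not for every library, as unenriched 5 (-0.50) lay below iridophore-enriched 4 (-0.01). The secreted factor gene angptl1a passed in 3 hybrids (adjusted p = 0.000153, 0.0339 and 2.09e-06 in aesculapii, albolineatus and kyathit), with -1.81 in iridophore-enriched libraries of aesculapii against 0.91, 0.90 and 1.45 in melanophore-enriched, xanthophore-enriched and unenriched libraries and -2.89 against 0.72, 1.41 and 0.64 in kyathit. In albolineatus the unenriched libraries stood apart instead (0.95, against -0.49, -0.43 and -0.30 in the sorted kinds). In nigrofasciatus angptl1a was tested without passing, although its iridophore-enriched libraries (-2.90, -2.14 and -2.08) lay below the others (-1.33 to 2.12). In aesculapii the sodium pump gene atp1a1b stood at -3.89 against 1.06, 1.57 and 1.63 (adjusted p = 0.000495), thy1 at -3.39 against -1.03, -0.92 and -0.55 (0.000153), and anxa1a at -1.19 against 0.66, 0.54 and 0.38 (0.00663). The F test of thy1 also passed in albolineatus (-3.77 against -1.62, -1.27 and -0.66, adjusted p = 0.00176) but not in kyathit or nigrofasciatus. In kyathit aox6 favoured D. rerio in xanthophore-enriched and unenriched libraries (-2.51 and -1.48) but not in iridophore-enriched and melanophore-enriched ones (0.77 and 0.50, adjusted p = 0.00689).

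Further genes with ratios that differed among kinds of library were txn in albolineatus (-4.73 in iridophore-enriched against -1.33, -1.62 and -0.46, adjusted p = 2.95e-05), with anxa3b, mdh1aa and sdr16c5b, and ugt5g1, fgl1 and clu in kyathit. In nigrofasciatus they were rnd3b, the lysosomal protease gene lgmn, myo5b, mfap5 and the purine synthesis gene adsl (-1.44 against 1.09, 0.83 and 0.22, adjusted p = 0.0332, but 0.0692 with a block for the replicate number and 0.0177 to 0.344 over the alternatives). In kyathit the block also ended the calls of the keratin gene krt18b (adjusted p = 0.0185, with it 0.0571, over the alternatives 0.0106 to 0.196) and the melanosome receptor gene gpr143 (0.0445, 0.183 and 0.0397 to 0.607). The reporter genes did not pass where they could be tested (tyrp1b and pnp4a in albolineatus and kyathit, pnp4a in nigrofasciatus, aox5 in kyathit, smallest adjusted p = 0.164). The F tests called 10 of 680 genes in aesculapii, 44 of 1604 in albolineatus (28 with the block), 39 of 2190 in kyathit (21) and 10 of 1471 in nigrofasciatus (6). Without replicate 3, 4 or 5, limma called 15, 6 and 10 genes in aesculapii, 21, 44 and 11 in albolineatus, 7, 4 and 6 in kyathit and 5, 0 and 0 in nigrofasciatus (53 and 62 at an unadjusted p under 0.05 without replicate 4 and 5).

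**Figure D4:**
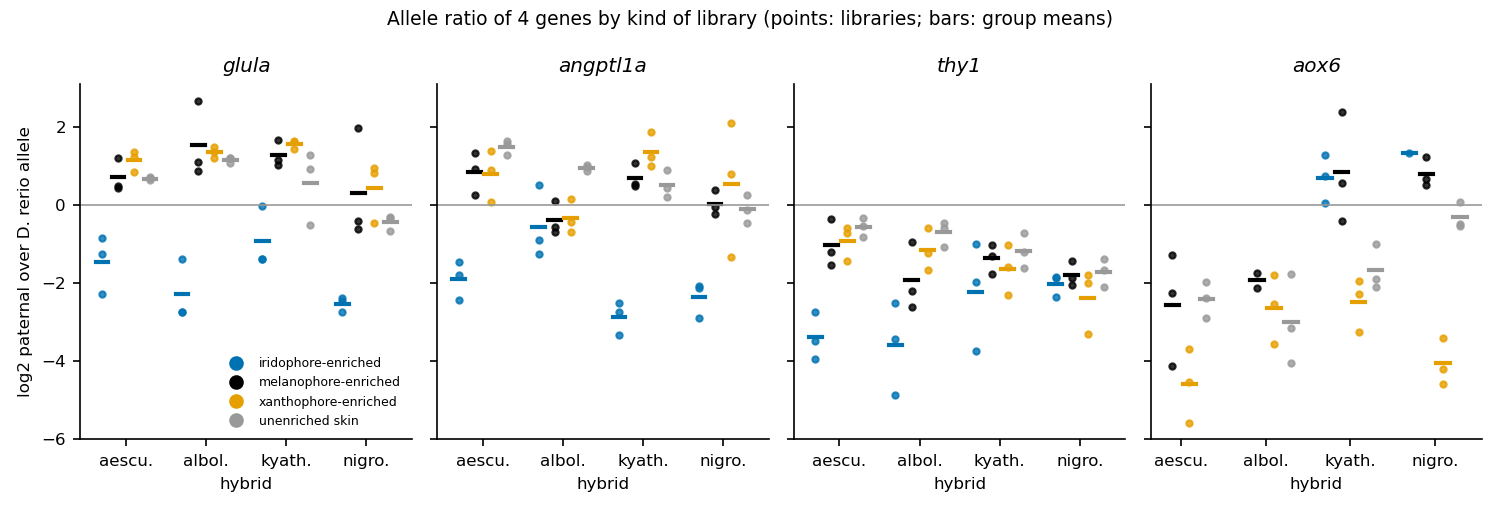
Centred log2 ratio of paternal over D. rerio allele (vertical axis) of glula, angptl1a, thy1 and aox6 in each library with 3 or more molecules of the gene, by hybrid and kind of library; points are libraries and bars are unweighted group means. For glula the iridophore-enriched group lies below the other kinds in all 4 hybrids.

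The last question was whether the paternal alleles differed from each other in their ratio to the common D. rerio allele. In iridophore-enriched libraries pnp4a did (-0.63, -0.85, 0.79 and 0.62 in aesculapii, albolineatus, kyathit and nigrofasciatus, 3 libraries each, adjusted p = 8.83e-06), as did lypc (-0.91, -2.93, -0.91 and -2.25, adjusted p = 1.17e-11) and bloc1s6 (0.69, -1.55 and -3.17 in the first 3, with under 1 molecule from nigrofasciatus, adjusted p = 3.33e-07). Of the pattern genes, csf1a (0.92, 0.92, -0.08 and -0.29, adjusted p = 0.0223), kitlga (0.13, 1.59, 0.69 and -0.28, adjusted p = 0.0104), cx39.4 (1.13, -2.05, 1.26 and 0.25, adjusted p = 0.0156) and thrab differed, while tjp1a did not pass (adjusted p = 0.664). For thrab the kyathit allele was listed at 0, so no fold is given. In melanophore-enriched libraries csf1a stood at 2.49 in nigrofasciatus against -0.05, 0.08 and -0.65 (adjusted p = 0.00453), and bace2 (-2.57 against -0.12, 0.26 and -0.49, adjusted p = 0.00251) and the nucleoside diphosphate kinase gene nme2b.1 (-2.71 against -0.50, 0.09 and -0.27, adjusted p = 0.000282) were low from that species. In xanthophore-enriched libraries bco1 (0.10, -0.09, 1.50 and -0.90, adjusted p = 0.0151), aox6 (adjusted p = 0.0268) and the sepiapterin reductase gene spra (adjusted p = 0.0462) differed.

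Among the genes with the smallest adjusted p, the actin gene actb2 stood at -2.68 in nigrofasciatus iridophore-enriched libraries against -0.32, -0.14 and 0.79 (adjusted p = 9.03e-12), and tmsb1, tpm4a and actr3 were each low from a single species. The thymosin gene tmsb4x was listed at 0 for the kyathit allele, and ppp1cbl and sat1a.2 for the aesculapii allele, so no fold is given for these. From the kyathit allele ppp1cbl was low as well (1.67 ± 1.53, SD, n = 3). Close copies of actb2 and of the thymosin genes leave open which copy the reads came from. An alignment preference for the D. rerio sequence could differ between the species pairs and give such differences too, which was not tested. For actb2 in nigrofasciatus, ratios were similar in iridophore-, melanophore- and xanthophore-enriched libraries (-2.68, -2.72 and -2.61). Either this preference or allele activity could give that. Ratios of csf1a in nigrofasciatus stood at -0.29 and 2.49 in iridophore- and melanophore-enriched libraries. That difference was not tested among kinds, and the second ratio rests on 11.1 D. rerio molecules over 3 libraries. The F tests called 695 of 2045 genes in iridophore-enriched, 336 of 1488 in melanophore-enriched and 129 of 792 in xanthophore-enriched libraries. Of the iridophore markers, 9 of 16 differed among hybrids in iridophore-enriched libraries (12 adjusted over the list alone), and of the melanophore markers 2 of 12 in melanophore-enriched ones (2 adjusted over the list alone). Of the pteridine and carotenoid genes, 3 of 8 differed in xanthophore-enriched libraries (4 adjusted over the list alone). Without replicate 4 or 5, 258 and 291 genes passed in iridophore-enriched libraries, 110 and 88 in melanophore-enriched and 49 and 58 in xanthophore-enriched libraries.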

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

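The paralog test of the heat shock genes and both tests of glula were chosen before the result each measures was seen; the other tests in this part, the splits of the samples included, were chosen only after the result was seen.

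The allele ratio differed among the 4 kinds of library for 10 genes in the aesculapii hybrid, 44 in albolineatus, 39 in kyathit and 10 in nigrofasciatus, by an F test of the difference itself. Of 100 splits of each hybrid's 12 libraries, the real one included, 4, 2, 1 and 1 gave as many genes. The highest others gave 17, 59, 20 and 4. Since other splits gave more genes than the real one in aesculapii and albolineatus, chance is not excluded for those counts. In kyathit and nigrofasciatus the real split gave the most genes, which argues against chance for the count but not for any single gene. With splits drawn within replicate numbers, 4, 1, 1 and 1 of 100 gave as many, and the highest others gave 20, 36, 13 and 7. The allele ratio differed among the 4 hybrids for 695 genes in iridophore-enriched, 336 in melanophore-enriched and 129 in xanthophore-enriched libraries, again by an F test. There 1 of 100 splits in each, the real one, gave as many genes, and the highest others gave 257, 159 and 68 (390, 228 and 113 within replicate numbers). This argues against chance as the source of those counts. It does not separate species differences in allele activity from an alignment preference that differs between paternal species, which was not tested.

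The heat shock genes hsp70.2, hsp70.3 and hsp70l favoured the D. rerio allele in all 4 hybrids, past the threshold in every kind of library. Reads passed between these close copies would cancel when hsp70.1, hsp70.2, hsp70.3 and hsp70l are summed, but the summed log2 ratio had a median of -2.22 over the 12 groups (-3.75 to -0.99, SD 0.87), which argues against sharing among the 4 as the whole cause. An alignment preference for the D. rerio sequence would shift a gene alike in every kind of library of a hybrid. Of 11 F tests of these genes among kinds, 0 passed with limma (smallest adjusted p = 0.0963), yet their ratios ranged over up to 2.22 between kinds, so no decision was reached and a preference stays open. A D. rerio allele that is more active after heat or handling stress stays open as well and was not tested.

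The paternal glula allele was lower in iridophore-enriched libraries than in the other kinds in all 4 hybrids, by -2.31, -3.65, -2.07 and -2.64 from the mean of the others. Different molecule numbers are argued against: with every library thinned to the shallowest (28, 62, 75 and 12 molecules, 200 thinnings), the differences were -2.36, -3.63, -2.07 and -2.68, the highest being -2.07. Summed with glulb and glulc, the differences shrank to -0.72, -0.46, -0.49 and -0.13, the highest being -0.13, which is in line with reads passing between the copies. The sum is diluted, however, because glula gave 32.4, 36.1, 18.9 and 21.5% of its molecules, so sharing between copies and a cell type difference in allele activity both stay open. The hybrids and cell types are named by the design, and no test here separates a regulatory difference from shared reads.

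In xanthophore-enriched libraries aox6 favoured D. rerio in all 4 hybrids. Reads passed between aox5 and aox6 are argued against as the whole cause, because the log2 ratio of both summed stayed at -2.60 ± 0.35, -0.92 ± 0.24, -1.93 ± 0.33 and -1.45 ± 0.22 (SE, n = 3), the highest being -0.92. An alignment preference that holds in every cell type is argued against in kyathit, where the ratio differed among kinds (adjusted p = 0.00689, 0.77 and 0.50 in iridophore- and melanophore-enriched libraries against -2.51 and -1.48 in xanthophore-enriched and unenriched ones). Without the sparse iridophore-enriched libraries, it is argued against in nigrofasciatus too (-4.07 ± 0.35 against 0.80 ± 0.22 in melanophore-enriched and -0.31 ± 0.20 in unenriched libraries, n = 3 each, Holm-adjusted p = 0.0107 by an exact permutation test, and a difference of -3.83 after thinning to 8 molecules). In aesculapii (-4.61 against -2.56 and -2.42, exact permutation test, Holm-adjusted p = 0.171) and albolineatus (-2.64 against -1.93 and -2.99, 0.529) that test did not pass and a preference stays open, as does, untested, a more active D. rerio aox6 allele in xanthophores. After thinning to 3 and 5 molecules, the difference went from -2.12 to -0.71 in aesculapii and from -0.18 to -0.38 in albolineatus.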

How the results depend on the processing

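The tests with other pseudocounts, with 1 spread for all libraries and without 2 libraries were chosen only after the result was seen, and the others were planned. Count-based tests and scalings were planned but not run, because the values are not counts, and centring by a trimmed mean stood in for the planned scaling of allele columns. Over the alternatives, 5449 of 5738 values of named genes kept their direction and side of the threshold, 236 fell short of it, 19 passed it and 34 reversed. The reversed values belonged to 18 results, of which 0 had passed with limma. Genes with too few molecules were not tested, which left 922 to 11772 genes per allele test, and where a gene lost its call the cause was not tested. Besides the calls already given with it, a block for the replicate number ended that of bco2b in melanophore-enriched aesculapii (adjusted p = 0.0588, over the alternatives 0.00613 to 0.0692). In melanophore-enriched kyathit libraries it brought aox5 (0.0492, over the alternatives 0.0224 to 0.155) and cx39.4 (0.0332, over the alternatives 0.0332 to 0.275) past the threshold.

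Without a filter on low values, more genes were tested, and 7469, 3809 and 3578 passed in the iridophore, melanophore and xanthophore enrichment contrasts; ratios differed among kinds for 32 genes in aesculapii, 75 in albolineatus and 17 in nigrofasciatus. With 10 molecules of each allele over the 12 libraries of the hybrid, 809 genes passed in unenriched aesculapii skin. With an estimated correlation, 7 list tests passed in place of 31. The block gave 613 genes in unenriched aesculapii and 2300 in unenriched albolineatus skin, and 28, 21 and 6 genes among kinds in albolineatus, kyathit and nigrofasciatus. With the pseudocount divided by 4 the last count was 5, and with 4 times the pseudocount it was 19, and 76 in albolineatus. With 1 spread for all libraries, 181 genes passed in xanthophore-enriched and 548 in unenriched aesculapii libraries. In albolineatus, 503 passed in melanophore-enriched, 459 in xanthophore-enriched and 1836 in unenriched libraries. In kyathit, 1142 passed in iridophore-enriched and 483 in unenriched libraries, and in nigrofasciatus 779 in unenriched ones. With that spread, 41 passed in all 4 hybrids in iridophore-enriched libraries, and 6, 6, 4 and 3 among kinds. Without kyathit unenriched 5 and nigrofasciatus unenriched 3, 1487 genes passed in unenriched kyathit skin.

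Leaving out each replicate number gave 539 to 789 genes for melanophore and 50 to 277 for xanthophore enrichment. For allele tests of iridophore-, melanophore-, xanthophore-enriched and unenriched libraries it gave 192 to 421, 103 to 196, 29 to 83 and 645 to 1015 in aesculapii, 547 to 891, 182 to 313, 137 to 167 and 2425 to 3258 in albolineatus, 1197 to 1362, 193 to 366, 140 to 304 and 96 to 1393 in kyathit, and 431 to 1067, 176 to 437, 157 to 317 and 448 to 1889 in nigrofasciatus. In all 4 hybrids, 26 to 46, 12 to 15 and 3 to 7 genes passed in iridophore-, melanophore- and xanthophore-enriched libraries. Among kinds, 6 to 15, 11 to 44, 4 to 7 and 0 to 5 passed in aesculapii, albolineatus, kyathit and nigrofasciatus (the 0 with limma came without replicate 4 and without 5, with 53 and 62 genes at an unadjusted p under 0.05), and among hybrids 258 to 537, 88 to 200 and 49 to 70 by cell type. Fewer libraries also meant fewer genes tested.

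Log2 ratios near 0 changed direction. In melanophore-enriched aesculapii libraries, tyrp1b moved from -0.01 to 0.16 with the block, 0.20 without centring, 0.07 with 4 times the pseudocount, 0.067 with 1 spread and 0.19 without the 2 shallowest libraries, and csf1a from -0.07 to 0.0071 without centring and 0.032 with 1 spread. In xanthophore-enriched albolineatus libraries, aox5 moved from 0.01 to -0.0295 with 4 times the pseudocount and -0.16 with 1 spread, and pnp4a from -0.15 to 0.0151 with 1 spread. Without the 2 unenriched libraries, kitlga moved to -0.065 in kyathit and aox5 to -0.059 in nigrofasciatus skin. Leaving out each replicate number gave tyrp1b -0.091 to 0.19 and csf1a -0.19 to 0.16 in melanophore-enriched, kitlga -0.0129 to 0.60 in iridophore-enriched, and csf1a -0.11 to 0.16 and kitlga -0.18 to 0.23 in unenriched aesculapii libraries. In albolineatus it gave aox5 -0.36 to 0.31 in xanthophore-enriched and -0.18 to 0.87 in melanophore-enriched libraries, csf1a -0.52 in the latter without replicate 5, and cx39.4 -1.16 to 1e-04 in skin. In kyathit it gave tyrp1b -0.0134 to 0.31 in iridophore-enriched, pnp4a -0.32 to 0.86 and csf1a -0.10 (without replicate 5) in xanthophore-enriched libraries, and tyrp1b -0.35 to 0.69, csf1a -0.82 to 0.25 and kitlga -0.064 to 0.25 in skin. In nigrofasciatus it gave cx39.4 0.97 without replicate 4 in xanthophore-enriched libraries and aox5 -0.059 to 0.77 in skin.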

Other observations

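The splits of the samples given here are tests chosen only after the result was seen, and the allele tests of unenriched skin were planned.

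In unenriched skin, the epidermal keratin genes cyt1l and cyt1, a pair of close copies, favoured the paternal allele in all 4 hybrids, cyt1 by 3.98 ± 0.33, 4.65 ± 0.31, 4.45 ± 0.35 and 4.00 ± 0.26 in aesculapii, albolineatus, kyathit and nigrofasciatus (log2, SE, n = 3 each). The RNA-binding protein gene elavl1a (2.33 ± 0.26, 2.39 ± 0.25, 2.88 ± 0.29 and 3.07 ± 0.30), fthl28 and pfn2 did so too. The D. rerio allele was higher for the cytochrome P450 gene cyp8b3 (-4.00 ± 0.21, -3.53 ± 0.25, -3.55 ± 0.60 and -2.58 ± 0.27), the mineralisation inhibitor gene mgp (-1.44 ± 0.18, -2.30 ± 0.33 and -2.84 ± 0.34 in the last 3, with under 1 molecule from aesculapii), the proteasome gene psmb12, ms4a17a.7 and myg1. For psmb12 the albolineatus allele, and for myg1 the aesculapii and albolineatus alleles, were listed at 0. Of the iridophore markers, lypc favoured D. rerio (-1.25 ± 0.23, -2.87 ± 0.19, -1.67 ± 0.22 and -1.81 ± 0.16). In all, 43 paternal and 81 D. rerio genes passed in all 4 hybrids of 4944 tested, where independent calls would give 1.93. As for the sorted libraries, that number is not a chance level. By hybrid, 541 paternal and 688 D. rerio of 7435 genes passed in aesculapii, 1787 and 1967 of 11772 in albolineatus, 370 and 450 of 5701 in kyathit and 619 and 868 of 6470 in nigrofasciatus. Without kyathit unenriched 5, the kyathit count was 1487, and leaving out replicate 3 or 4 there gave 133 and 96.

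Values of mitochondrially encoded genes lay almost only with D. rerio, the mother of all hybrids. The mean D. rerio value of mt-co2 over the 48 libraries was 57732 against a highest paternal value of 5, that of mt-cyb 44383 against 4 and that of mt-co3 34958 against 2. Of 13 such genes, 6 had any paternal value. Over both tables, 38 genes had no paternal and 11 no D. rerio value in any library, and these were not tested. The globin gene hbba1 stood at 59548 in nigrofasciatus unenriched 3 against a median of 5593 in the 10 unenriched libraries other than this one and kyathit 5.

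Each allele test has only 4 splits of its 3 libraries (the alleles exchanged in none or in 1 of them), too few for a share under 0.05. The real split gave 425, 227, 81 and 1229 genes in aesculapii (iridophore-, melanophore-, xanthophore-enriched, unenriched), and the highest other 4, 10, 0 and 0. In albolineatus they gave 1019, 334, 277 and 3754 against 1, 3, 2 and 0, in kyathit 2111, 537, 472 and 820 against 1, 7, 5 and 239, and in nigrofasciatus 1206, 550, 429 and 1487 against 16, 6, 5 and 8. For genes unequal in all 4 hybrids, 1 of 100 splits, the real one, gave 66, 23 and 18 genes. The highest other gave 0 in each cell type. Exchanging the alleles in 1 of 3 libraries already removed nearly all calls of a sorted group, so that outcome was close to fixed in advance. It cannot decide whether the agreement between hybrids exceeded chance. For enrichment, with the 24 libraries compared, the real split gave 2722, 1032 and 403 genes in the iridophore, melanophore and xanthophore contrasts. The highest other gave 1961, 503 and 176 (2011, 776 and 300 within replicate numbers). Only 1 of 100 splits each, the real one, gave as many, which argues against chance as the source of these counts.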
